A study of Mus musculus with 9 samples.

How the data were processed

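RNA was isolated from flash-frozen mouse thyroids with TRIzol and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols; no label states whether the counting used strand. The values used here are the raw gene-level read counts of 9 libraries as deposited by the authors, as whole numbers with no normalization. The submitters' processing notes name STAR 2.4, HTSeq 0.6.1, DESeq2 and the genome build mm9, with no role or order. Reads from overlapping genes, antisense partners and near-identical copies cannot be told apart in such counts, and genes affected are called uncertain where named. Total counts run from 33666251 to 89553766, and the Arid2-labelled libraries are the deepest. The table holds 33924 named genes, of which 8005 have 0 counts in all libraries. Libraries of 1 group differed far beyond counting error (chi-square per degree of freedom from 51.2 to 132 over gene counts), so none is a copy of another. PCR reads without molecular identifiers are not independent molecules, so counting intervals cover counting error only.

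Groups were taken from the genotype labels. Differential expression was tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr by group) in R 4.3.3, with all 9 libraries in 1 fit of 3 group means, no covariate and 6 residual degrees of freedom. The filter kept 17079 genes, the common dispersion was 0.0776 and the prior degrees of freedom were 3.19. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold, and fold changes are on the log2 scale with the standard error from the fold and its F statistic. Levels are TMM-scaled CPM computed here. The targeted genes also had an exact two-sided permutation test of log2 CPM. In all, 44 gene lists of pathways, complexes and cell types were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the 42 lists with at least 3 tested members; camera with an estimated correlation and fry were alternatives. Of 593 list entries, 584 were found in the table under a symbol or alias.

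The groups, lists, tests, a first set of variations and the rule for named genes were fixed before the data were examined. The rule names Arid2 and Smarcb1; in each comparison the 6 called genes with the largest rise and the 6 with the largest fall, with an average log2 CPM of at least 1, no overlap of the groups and a gene symbol that is not a provisional one; the thyroid transcription factors and main genes of thyroid hormone production; and up to 4 members of every other list with the smallest adjusted p. Provisional symbols were screened by a fixed set of forms, which did not cover clone-based names such as AC115697.1 or BC002163, or microRNA names that start with mmu. Markers of neighbouring tissues and of sex are members of the lists. Genes named outside the rule are said to be so, and some genes the rule would name are not reported here.

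Variations of these choices were DESeq2 size factors, upper-quartile scaling and library totals in place of TMM, no filter or a CPM of at least 1 in at least 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, a fit of only the 6 libraries compared, an adjusted p under 0.01, a fold of at least 2, a robust spread, a fit without the cell-type genes, and leaving out each library in turn. After the data were seen, 5 were added: removal of each library's trend over GC content (a natural spline with 5 degrees of freedom, used as an offset), a covariate of the mean log2(CPM + 1) of Pth, Gcm2 and Casr, both together, omission of the 2 libraries with thymus markers, and thinning of all libraries to the smallest total. GC content came from the longest transcript of each gene in the GRCm38 annotation, matched by symbol or synonym for 97.3% of the tested genes; no coordinates are printed, since the build differs from mm9.

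The edgeR step was tested on simulated counts with the real means and library sizes and 200 changed genes. For Arid2-labelled against wild type it recovered 44 of 100 genes changed 2-fold and 88 of 100 changed 4-fold with 5 false calls over 16909 genes. For Smarcb1-labelled against wild type it recovered 40 and 90 with 10 false calls over 16904 genes, and for Smarcb1-labelled against Arid2-labelled 47 and 93 with 10 over 16888. Genes were drawn independently, with no difference of tissue markers, sex or GC trend between libraries, so these false calls leave out such structure. The GC step was run on 16944 simulated unchanged genes with a GC trend. It took the median log2 fold change above 60% GC from -0.63 to 0.01 and under 40% GC from 0.63 to 0.002. Before and after it 0 genes were called. Shared controls were simulated 20 times.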

Results

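RNA sequencing was carried out on whole thyroid tissue of mice in 3 genotype groups of 3 libraries each: wild type, libraries labelled Arid2 KO and libraries labelled Smarcb1 KO. Arid2 and Smarcb1 encode subunits of SWI/SNF, a family of chromatin remodelling complexes; Smarcb1 is a core subunit and Arid2 belongs to the PBAF form. The question is how thyroid transcript levels differ between tissue with and without each subunit. Total counts were 34045321, 33701524 and 33666251 in the wild-type libraries, 89553766, 67482861 and 61179297 in the Arid2-labelled libraries and 39883807, 41362640 and 38644867 in the Smarcb1-labelled libraries. Tg, the gene of thyroglobulin, the precursor protein of thyroid hormone, was the most abundant gene in all 9 libraries, with 24.1% to 30.8% of the counts. The labels do not say whether the 3 libraries of a group come from separate animals, so the p-values measure only the spread between these libraries.

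The targeted genes were read first. Arid2 stood at 94.6, 77.7 and 59.9 CPM (counts scaled to library size) in Arid2-labelled replicates 1, 2 and 3, and at 68.9, 75.0 and 67.8 CPM in the wild-type libraries. The log2 fold change was 0.13 (SE 0.16, adjusted p = 0.745; exact two-sided permutation p = 0.7, n = 3 against 3). In the Smarcb1-labelled libraries Arid2 stood at 91.3, 77.2 and 93.8 CPM. Smarcb1 stood at 47.5, 53.7 and 59.4 CPM in the Smarcb1-labelled libraries, at 65.9, 71.7 and 69.3 CPM in wild type and at 57.3, 59.4 and 64.6 CPM in the Arid2-labelled libraries. Its log2 fold change against wild type was -0.36 (SE 0.11, adjusted p = 0.0651), lower in 3 of 3 libraries, with an exact permutation p of 0.1, the smallest that 3 against 3 can give. Whole-gene counts include exons outside a deletion, and whole tissue includes cells outside any targeted cell type, so these values neither bear out nor exclude the labels. The groups are therefore called Arid2-labelled and Smarcb1-labelled throughout.

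**Figure D1:**
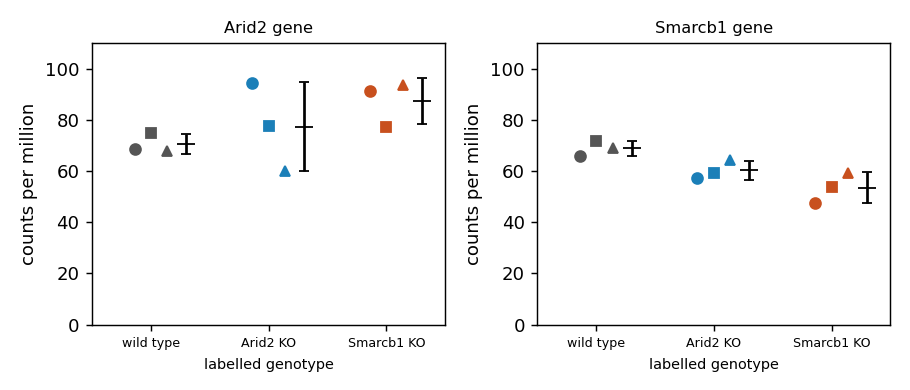
Levels of the Arid2 and Smarcb1 genes in CPM on the vertical axis, in each library of the 3 labelled genotypes (circle, square and triangle for replicates 1, 2 and 3; bar for mean and SD, n = 3). Arid2 averages 77.4 in the Arid2-labelled and 70.5 in the wild-type libraries, and Smarcb1 averages 53.5 in the Smarcb1-labelled and 69.0 in the wild-type libraries.

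Markers of neighbouring tissues differed between libraries. Pth, the parathyroid hormone gene, stood at 16751, 5892 and 9307 CPM in the Smarcb1-labelled libraries, at 1199, 4172 and 0.0297 CPM in wild type and at 1531, 1436 and 0.129 CPM in the Arid2-labelled libraries. Rag1, a recombinase gene of developing lymphocytes, stood at 502.0 CPM in Arid2-labelled replicate 1 and 52.6 CPM in Smarcb1-labelled replicate 2, and at 0.145 CPM or less in the other 7. Myh4, a skeletal muscle myosin, ranged from 3.07 CPM in wild-type replicate 2 to 699.6 CPM in Arid2-labelled replicate 3. Xist, the RNA of X inactivation, stood at 809 CPM in Smarcb1-labelled replicate 3, where the Y-linked Ddx3y had 0 counts, and at 2.60 CPM or less in the other libraries. Hba-a1, a haemoglobin gene, stood at 471, 68.6 and 319 CPM in wild type and at 12.5, 30.5 and 10.1 CPM in the Smarcb1-labelled libraries.

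**Figure D2:**
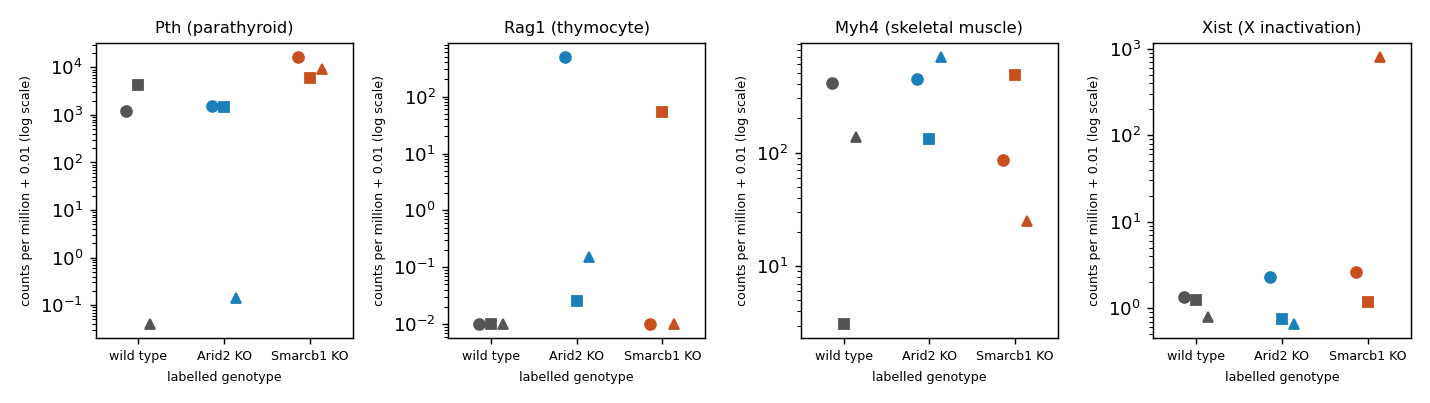
Levels of 4 marker genes in CPM plus 0.01 on a log scale, in each library of the 3 labelled genotypes (circle, square and triangle for replicates 1, 2 and 3). Pth is near 0 in 1 wild-type and 1 Arid2-labelled library and high in all 3 Smarcb1-labelled libraries, Rag1 is high in 2 libraries and Xist in 1.

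In the comparison of Arid2-labelled with wild-type thyroid, Cadm3, which encodes a cell adhesion molecule, rose from 26.1 ± 1.68 to 159.9 ± 36.3 CPM (mean ± SD, n = 3 each), a log2 fold change of 2.61 (SE 0.20, adjusted p = 0.00149). Duoxa1, whose product is a maturation factor of the hydrogen peroxide generator Duox1, fell from 17.7 ± 5.36 to 2.97 ± 0.589 CPM (log2 fold change -2.58, SE 0.38, adjusted p = 0.0269). Its call ended without any 1 of the 3 Arid2-labelled or the 3 wild-type libraries. Scgb3a1, a secretoglobin of airway secretory cells, rose from 0.384 ± 0.132 to 17.2 ± 5.17 CPM (log2 fold change 5.47, SE 0.45, adjusted p = 0.00261). Of the 17079 genes tested, 95 passed an adjusted p under 0.05, 40 of them higher and 55 lower.

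Besides Cadm3, the largest rises under the naming rule were Bbox1 (3.55, SE 0.54), an enzyme of carnitine synthesis, Darc (2.47, SE 0.27), S100a5 (2.13, SE 0.29), the phosphodiesterase gene Pde4c (2.08, SE 0.33) and the potassium channel gene Kcnt1 (1.94, SE 0.31). Darc neighbours Cadm3, and its count is uncertain where the annotated genes share reads. Besides Duoxa1, the largest falls were those of mmu-mir-689-2 (-2.96), AC115697.1 (-2.44), AC113316.1 (-2.31), Ankrd43 (-1.96) and Spon2 (-1.93), a secreted matrix protein. The counts of mmu-mir-689-2, AC115697.1 and AC113316.1, which have microRNA or clone-based names, are uncertain, since shared reads were not checked. Their levels moved together over the libraries, each highest in wild-type replicate 3 and lowest in Smarcb1-labelled replicate 3. They need not be separate changes. The number of called genes was 45, 5 and 14 without Arid2-labelled replicate 1, 2 or 3, was 12, 30 and 56 without wild-type replicate 1, 2 or 3, and was 167 without Smarcb1-labelled replicate 1, which enters through the shared spread. Of the 16 named genes that were called, Cadm3 and Scgb3a1 passed in all 9 fits that left out 1 library. Removal of Arid2-labelled replicates 1, 2 and 3 lost 9, 14 and 13 calls, of wild-type replicates 1, 2 and 3 lost 14, 11 and 7, and of Smarcb1-labelled replicate 3 lost 3.

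Among 24 tested genes of thyroid hormone production, 1, Duoxa1, fell and 0 rose over all genes tested; adjusted over the list alone, 4 were lower and 1 higher. Slc5a5, the sodium iodide symporter that takes up iodide, stood at 127.4 ± 19.9 CPM against 467 ± 72.7 in wild type, lower in 3 of 3 libraries, without passing (log2 fold change -1.87, SE 0.43, adjusted p = 0.0944). Tg (-0.01, SE 0.29, adjusted p = 0.994) and the thyrotropin receptor gene Tshr (-0.55, SE 0.24, adjusted p = 0.339) did not pass either. The list as a whole was lower by the camera test (median log2 fold change -0.22, adjusted p = 0.0441; adjusted p = 0.805 with an estimated correlation). That call ended without Arid2-labelled replicate 1 (adjusted p = 0.213) or 3 (0.0546), Smarcb1-labelled replicate 2 (0.0676), and wild-type replicate 1 (0.179), 2 (0.0858) or 3 (0.0575).

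All 30 cell-cycle genes had positive fold changes in the Arid2-labelled libraries, with a median log2 fold change of 1.33. By edgeR 0 passed over all genes tested (27 at an unadjusted p under 0.05, and 19 by DESeq2), and 27 were higher adjusted over the list alone; the mitotic kinase Cdk1, for example, stood at 11.4 ± 3.83 against 4.84 ± 1.09 CPM (1.23, SE 0.29, adjusted p = 0.0978). The list was called higher by camera (adjusted p = 4.46e-16; adjusted p = 0.805 with an estimated correlation). Arid2-labelled replicate 1, with Rag1 at 502.0 CPM, had the highest mean log2 level of the list, and without it the median was 0.93, the camera adjusted p was 3.02e-13 and 12 genes were higher adjusted over the list alone.

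Camera called 6 further lists higher and 1 lower, none of them with an estimated correlation. Of 10 airway epithelium genes 3 rose, Scgb3a1, Bpifb1 (4.85, SE 0.66) and the mucin gene Muc5b (4.26, SE 0.65), and 5 were higher adjusted over the list alone (camera adjusted p = 6.84e-05; adjusted p = 0.805 with an estimated correlation). Of 12 endothelial genes 11 were positive and Emcn, an endothelial sialomucin, rose (0.83, SE 0.12, adjusted p = 0.0269), with 8 higher adjusted over the list alone (camera adjusted p = 6.84e-05; adjusted p = 0.842 with an estimated correlation). All 10 fibroblast genes were negative, 0 passed over all genes tested by edgeR (5 at an unadjusted p under 0.05, and 4 by DESeq2) and 5 were lower adjusted over the list alone (camera adjusted p = 0.000161; adjusted p = 0.805 with an estimated correlation). All 8 smooth muscle and pericyte genes were positive with 0 calls by edgeR (3 at an unadjusted p under 0.05, and 1 by DESeq2), and 1 was higher adjusted over the list alone (camera adjusted p = 0.0149; adjusted p = 0.842 with an estimated correlation); without Arid2-labelled replicate 3 or wild-type replicate 1 the adjusted p was 0.0919 or 0.0693.

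Of 15 circadian clock genes 0 passed by edgeR (9 at an unadjusted p under 0.05, and 5 by DESeq2) and 6 were higher adjusted over the list alone (camera adjusted p = 0.0128; adjusted p = 0.842 with an estimated correlation). All 15 skeletal muscle genes were positive, with 0 calls by edgeR either way of adjusting, 1 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.00568; adjusted p = 0.842 with an estimated correlation); wild-type replicate 2 had the lowest level of this list, and without it the adjusted p was 0.384, and without Arid2-labelled replicate 3 it was 0.0546. Of 8 cartilage genes 0 passed by edgeR (3 at an unadjusted p under 0.05, and 2 by DESeq2) and 3 were higher adjusted over the list alone (camera adjusted p = 0.0435; adjusted p = 0.805 with an estimated correlation), and the call ended without Arid2-labelled replicate 2 (0.0514), Smarcb1-labelled replicate 1 (0.0655) or wild-type replicate 1 (0.179), and with all libraries thinned to equal depth (0.150). Acan, the cartilage proteoglycan aggrecan, had 18, 14 and 56 counts in Arid2-labelled replicates 1, 2 and 3 (0.198, 0.219 and 0.900 CPM) and 2 counts over the wild-type libraries. The ratio of the summed counts was 20.6 with a 95% counting interval of 5.55 to 173, which leaves out the spread between libraries, and replicate 3 holds most of the counts.

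**Figure D3:**
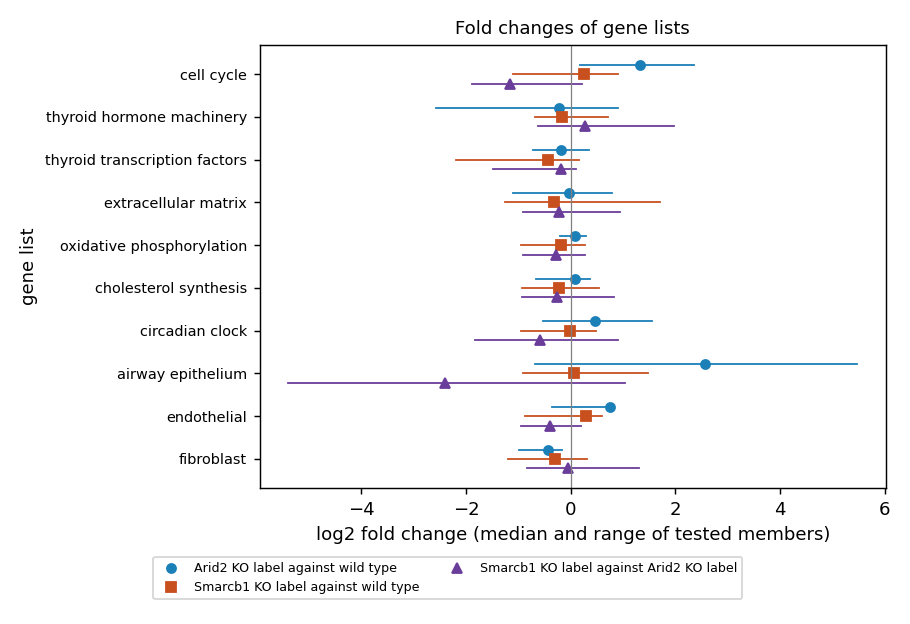
Log2 fold changes of 10 gene lists on the horizontal axis, with the median (marker) and the range (line) of the tested members for each of the 3 comparisons. The cell-cycle median is 1.33 for Arid2-labelled against wild type, 0.26 for Smarcb1-labelled against wild type and -1.17 for Smarcb1-labelled against Arid2-labelled.

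In the comparison of Smarcb1-labelled with wild-type thyroid, Foxe1, a transcription factor of thyroid development, fell from 240.02 ± 38.8 to 52.4 ± 8.65 CPM, a log2 fold change of -2.19 (SE 0.19, adjusted p = 0.00102, n = 3 each). Junb, an immediate early transcription factor gene, fell from 21.1 ± 1.96 to 4.62 ± 2.70 CPM (-2.18, SE 0.34, adjusted p = 0.00950), and the tight junction gene Cldn3 fell from 109.6 ± 2.62 to 32.0 ± 11.3 CPM (-1.78, SE 0.24, adjusted p = 0.00597). The collagen genes Col1a1 and Col5a1 fell as well (-1.06, SE 0.19, and -0.95, SE 0.13). Foxe1, Junb, Cldn3 and Col5a1 passed in all 9 fits that left out 1 library, and Col1a1 did not without Smarcb1-labelled replicates 1 or 3 or wild-type replicate 1. In all, 1349 genes passed, 368 higher and 981 lower.

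The largest rises under the naming rule were Lect1 (5.49, SE 1.02), a cartilage matrix gene, Grem1 (2.35, SE 0.50), a secreted antagonist of bone morphogenetic proteins, Qpct (2.08, SE 0.47), Sytl4 (1.84, SE 0.43), Flrt2 (1.82, SE 0.39) and Rims2 (1.79, SE 0.35). Lect1 stood at 181.5, 6.09 and 112.5 CPM in Smarcb1-labelled replicates 1, 2 and 3 against 2.22 ± 0.352. Qpct, Sytl4 and Flrt2 were highest among the wild-type libraries in replicate 2, with Pth at 4172 CPM, and lowest in replicate 3, with Pth at 0.0297 CPM, and none of the 6 passed with the parathyroid covariate. Under it the folds were 5.46 for Lect1, 2.50 for Grem1 and 2.05 for Rims2. Those of Qpct (1.37), Sytl4 (1.32) and Flrt2 (1.31) were smaller than without it. The largest falls were mmu-mir-689-2 (-5.48, SE 0.46), Amdhd1 (-5.22, SE 0.99), an enzyme of histidine breakdown, Scand1 (-4.92, SE 0.29), AC115697.1 (-4.13, SE 0.45), Hba-a1 (-4.01, SE 0.74) and Pcsk1n (-3.97, SE 0.46). Amdhd1 stood at 1.12, 27.9 and 16.5 CPM in wild-type replicates 1, 2 and 3 and at 0.543 CPM or less in the Smarcb1-labelled libraries. Its call ended without Smarcb1-labelled replicate 1 or 3. Hba-a1 shares reads with a near-identical globin copy and is uncertain. For mmu-mir-689-2 and AC115697.1 shared reads were not checked, so they are uncertain as well.

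Fold changes in this comparison varied with GC content. The median log2 fold change was -0.73 over the 678 genes above 60% GC and 0.34 over those under 40% GC. Above 60% GC, the median deviation from each gene's 9-library mean was negative in all 3 Smarcb1-labelled libraries (-0.86, -0.20 and -0.47). With each library's trend over GC content removed, an alternative chosen after the data were seen, 418 genes passed, 347 of them among the 1349. Foxe1 (-1.31), Junb (-1.40), Cldn3 (-0.95) and Scand1 (-3.35) passed, and Col1a1 (-0.60), Col5a1 (-0.55) and Grem1 (2.11) did not. With the parathyroid marker level as a covariate, also chosen after the data were seen, 197 genes passed, Foxe1, Junb, Cldn3, Col5a1 and Scand1 among them, and Col1a1 (-0.81), Lect1 (5.46), Grem1 (2.50) and Hba-a1 (-3.51) not. Under the covariate the median fold of the higher genes went from 0.84 to 0.79 and of the lower genes from -0.83 to -0.79, while the median SE rose from 0.187 to 0.219 and from 0.164 to 0.193. The number of called genes was 721, 2538 and 344 without Smarcb1-labelled replicate 1, 2 or 3, was 371, 543 and 545 without wild-type replicate 1, 2 or 3, and was 657 without Arid2-labelled replicate 2; 2166 passed without both thymus-marked libraries. Lower genes were 72.7% of the calls and, without Smarcb1-labelled replicate 2, 58.4% of the larger number of calls and 70.8% of the 1349 genes with the smallest p.

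**Figure D4:**
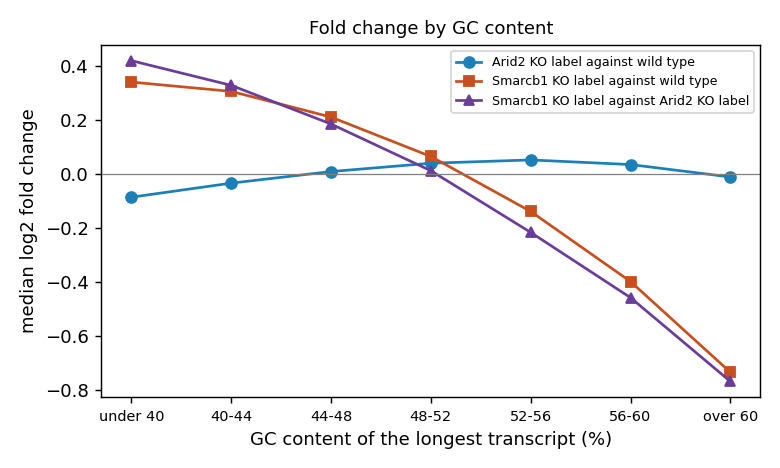
Median log2 fold change on the vertical axis of the tested genes in 7 classes of GC content (percent, horizontal axis), for each of the 3 comparisons. Both comparisons of the Smarcb1-labelled libraries fall from 0.34 and 0.42 under 40% GC to -0.73 and -0.77 above 60%, while the Arid2-labelled against wild-type medians lie between -0.09 and 0.05.

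Among the thyroid transcription factors, 1 of 5 passed over all genes tested, Foxe1, and 3 were lower adjusted over the list alone; Pax8 (-0.48, SE 0.15, adjusted p = 0.0763) and Nkx2-1 (-0.44, SE 0.16, adjusted p = 0.111) did not pass over all genes. Of 24 genes of thyroid hormone production 1 rose, Lrp2, an endocytic receptor that binds thyroglobulin (0.72, SE 0.17, adjusted p = 0.0386), and 0 passed adjusted over the list alone; without any 1 library other than Smarcb1-labelled replicate 2 Lrp2 did not pass. Slc5a5 (-0.54, SE 0.41) and Tg (-0.09, SE 0.29) did not pass. Camera called neither list (adjusted p = 0.197 and 0.502).

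Of 27 extracellular matrix genes 5 fell and 1 rose, and adjusted over the list alone 9 were lower and 1 higher. Loxl1, a crosslinking enzyme of elastic fibres, fell by 1.27 (SE 0.20) and the gelatinase gene Mmp2 fell by 0.48 (SE 0.10) on the log2 scale, beside Col1a1 and Col5a1. The list was called lower by camera (median -0.33, adjusted p = 0.0226; adjusted p = 0.973 with an estimated correlation). The call ended with the GC trend removed (adjusted p = 0.202), without Smarcb1-labelled replicate 1 (0.0559) and without wild-type replicate 3 (0.248), and Col1a1, Col5a1, Loxl1 and Mmp2 each lost their calls with the trend removed.

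Of 22 targets of mitogen-activated protein kinase signalling, Spred3 (1.16) and Etv1 (1.13) rose and Spry1 (-0.59) and Phlda1 (-0.71) fell, with 2 higher and 3 lower adjusted over the list alone. Of 16 immediate early genes Fosb rose (1.96) and Junb and Ier2 (-0.95) fell, and the same numbers passed adjusted over the list alone. Fosb was near the floor, with 20, 78 and 31 counts in Smarcb1-labelled replicates 1, 2 and 3 against 11, 6 and 10 in wild type. Its call ended without any 1 library other than Smarcb1-labelled replicate 1. Of 18 cholesterol synthesis genes 3 fell, Mvk (-0.93), Mvd (-0.72) and the regulator Srebf2 (-0.67), and 1 rose, with 4 lower and 1 higher adjusted over the list alone. Of 19 epithelial junction genes Cldn3, Tjp3 (-0.92) and Cldn7 (-0.50) fell and 7 were lower adjusted over the list alone. Of 30 oxidative phosphorylation genes Ndufa2 (-0.95) and Cox5a (-0.84) fell and 3 were lower adjusted over the list alone. Of 30 cell-cycle genes Mcm6, a subunit of the replicative helicase, fell (-1.10), the same number as adjusted over the list alone. Camera called none of these 6 lists (adjusted p from 0.0816 for oxidative phosphorylation to 0.902 for immediate early genes).

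Several of these lists hold cell types whose markers differed between libraries. Of 12 endothelial genes Emcn (0.58) and Tek (0.61) rose, with 3 higher adjusted over the list alone; of 10 fibroblast genes Clec3b (-1.20), Serpinf1 (-0.61) and Dpep1 (-0.84) fell, with 4 lower adjusted over the list alone. Of 5 blood genes Hba-a1 and Hbb-b1 (-2.51) fell, with 3 lower adjusted over the list alone. Both named genes are uncertain where near-identical globin copies share reads. Camera called none of the 3 lists (adjusted p = 0.386, 0.137 and 0.197). Of 25 other SWI/SNF subunit genes Smarcc1 rose (0.48, SE 0.12, adjusted p = 0.0486). Without any 1 library other than Arid2-labelled replicate 1 Smarcc1 did not pass. Adjusted over the list alone 2 were higher and 2 lower (camera adjusted p = 0.803). Of the 54 named genes that were called, the GC-trend removal lost 38 and the parathyroid covariate 43. Leaving out 1 library lost 28, 5 and 41 for Smarcb1-labelled replicates 1, 2 and 3, 39, 25 and 32 for wild-type replicates 1, 2 and 3, and 11, 22 and 9 for Arid2-labelled replicates 1, 2 and 3.

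The direct comparison of Smarcb1-labelled with Arid2-labelled thyroid tests whether the effects of the genotype labels differ, since the wild-type libraries cancel. Cadm3 was lower in the Smarcb1-labelled libraries, at 19.6 ± 3.83 against 159.9 ± 36.3 CPM (-3.03, SE 0.20, adjusted p = 0.000621), as was Srd5a1, a steroid 5-alpha-reductase gene (-3.36, SE 0.24, adjusted p = 0.000621). Foxe1 was lower too (-1.48, SE 0.19, adjusted p = 0.00470), and Duoxa1 was higher (1.98, SE 0.37, adjusted p = 0.0141), a call that ended without Arid2-labelled replicates 2 or 3. Ctgf, a matricellular growth factor gene and Hippo pathway target, was higher at 249.9 ± 84.2 against 76.9 ± 22.4 CPM (1.70, SE 0.26, adjusted p = 0.00795). In all, 2779 genes passed, 1187 higher and 1592 lower. The majority turned to 1537 higher and 1417 lower with upper-quartile scaling and to 1258 and 1148 with library totals.

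The largest differences upward under the naming rule were BC002163 (4.29, SE 0.95), the potassium channel gene Kcnj2 (2.76, SE 0.52), the water channel gene Aqp4 (2.68, SE 0.60), Ccdc67 (2.64, SE 0.57), Pkib (2.60, SE 0.56) and Tspan6 (2.58, SE 0.55). All 6 were highest among the wild-type libraries in replicate 2, with Pth at 4172 CPM, and lowest in replicate 3, with Pth at 0.0297 CPM (Tspan6 71.4, 178.7 and 47.0 CPM in replicates 1, 2 and 3). Among the Arid2-labelled libraries 5 were lowest in replicate 3, with Pth at 0.129 CPM, but BC002163 was highest there (0.462, 0.532 and 0.626 CPM). Shared reads were not checked for BC002163, which has a clone-based name, so its count is uncertain. None of the 6 passed with the parathyroid covariate (Tspan6 1.64, adjusted p = 0.0878). Beside Cadm3 and Srd5a1, those downward were Amdhd1 (-5.01, SE 0.98), Scand1 (-4.16, SE 0.28), Hba-a1 (-3.19, SE 0.72) and the mitochondrial ribosomal protein gene Mrps34 (-3.10, SE 0.30). Asns, asparagine synthetase, was higher (1.33, SE 0.17). The median log2 fold change was -0.77 above 60% GC and 0.42 under 40% GC, and 1075 genes passed with the GC trend removed and 145 with the parathyroid covariate; Cadm3, Srd5a1, Scand1, Mrps34, Foxe1 and Asns passed in both. Of the 75 named genes that were called the GC-trend removal lost 31, the covariate 64 and both together 66. The number of called genes was 1761, 800 and 395 without Arid2-labelled replicate 1, 2 or 3, was 1069, 4411 and 956 without Smarcb1-labelled replicate 1, 2 or 3, and was 1677 without wild-type replicate 1. Of the 75, those removals lost 18, 43, 57, 41, 5, 44 and 15.

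Of 30 cell-cycle genes 11 were lower in the Smarcb1-labelled than in the Arid2-labelled libraries, among them Mcm6 (-1.80, SE 0.23, adjusted p = 0.00490), Ccnb2 (-1.89, SE 0.40), Plk1 (-1.77, SE 0.39) and Cdc20 (-1.57, SE 0.32), and 22 were lower adjusted over the list alone. The list was called lower by camera (median -1.17, adjusted p = 7.46e-07; adjusted p = 0.920 with an estimated correlation). Without Arid2-labelled replicate 1, the library with Rag1 at 502.0 CPM, 3 of the 30 passed over all genes and the median was -0.60. Without that library and Smarcb1-labelled replicate 2, the other with Rag1 above 1 CPM, 12 passed and the median was -0.80.

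Of 10 airway epithelium genes 3 were lower, Scgb3a1 (-5.16, SE 0.44), Bpifb1 (-5.40, SE 0.68) and Muc5b (-3.17, SE 0.59), and 6 adjusted over the list alone (camera adjusted p = 0.00121; adjusted p = 0.920 with an estimated correlation). Of 30 oxidative phosphorylation genes 4 were lower, Ndufa2 (-0.87), Cox5a (-0.91), Cox5b (-0.83) and Cox4i1 (-0.65), the same number as adjusted over the list alone (camera adjusted p = 0.0137; adjusted p = 0.920 with an estimated correlation), and the call ended without Arid2-labelled replicate 3 (0.231) or Smarcb1-labelled replicate 3 (0.0670). Of 15 circadian clock genes 4 were lower, among them Dbp (-1.31) and Per3 (-1.06), and 1 was higher, with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0357; adjusted p = 0.920 with an estimated correlation). That call ended with the GC trend removed (adjusted p = 0.0697), without both thymus-marked libraries (0.133), and without Arid2-labelled replicate 2 (0.0953) or Smarcb1-labelled replicates 1 (0.119) or 2 (0.109). Of 24 genes of thyroid hormone production 2 were higher, Duoxa1 and Lrp2 (0.94), and 1 was lower, the same numbers as adjusted over the list alone, with no camera call (adjusted p = 0.547).

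Against wild type, 28 genes passed in both labelled groups in the same direction, 8 higher and 20 lower, and 2 passed in opposite directions, among them Sardh, higher in the Arid2-labelled (0.73) and lower in the Smarcb1-labelled libraries (-0.50). Sardh was singled out after its values were seen. The 20 lower genes include mmu-mir-689-2, AC115697.1 and AC113316.1, which need not be separate changes. Independent lists of these sizes would share 0.862 higher and 3.16 lower genes. Unchanged groups simulated against the same wild-type libraries called too few genes (0.2 and 0.1 higher on average) for their shared count to be a yardstick for the 28. Across genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.345 and a Spearman correlation of 0.210, where simulated unchanged groups gave a Pearson mean of 0.512 (0.450 to 0.565). The covariance was 0.150 against a simulated 0.0792, a difference of 0.0712. With 3 wild-type libraries the controls cannot be divided into parts of at least 2, so part of the overlap may come from the shared controls. The shared count was 10, 1 and 2 without Arid2-labelled replicate 1, 2 or 3, was 5, 8 and 18 without wild-type replicate 1, 2 or 3, and was 13 without both thymus-marked libraries. The correlation was 0.174 without Arid2-labelled replicate 1, 0.127 without Smarcb1-labelled replicate 2 and 0.0966 without both, and reached 0.474 and 0.543 without Arid2-labelled replicates 2 and 3, 0.569 and 0.510 without Smarcb1-labelled replicates 1 and 3 and 0.590, 0.535 and 0.542 without wild-type replicates 1, 2 and 3.

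**Figure D5:**
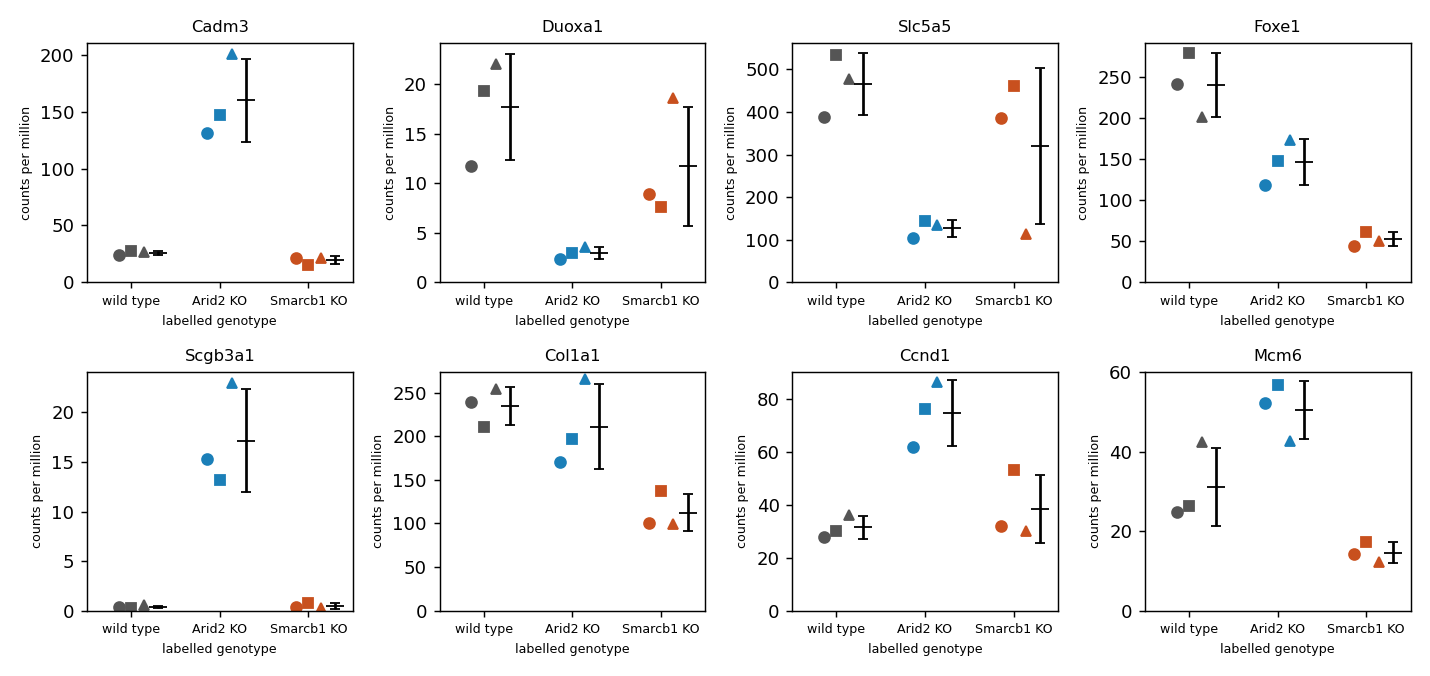
Levels of 8 named genes in CPM on the vertical axis, in each library of the 3 labelled genotypes (circle, square and triangle for replicates 1, 2 and 3; bar for mean and SD, n = 3). Cadm3 lies between 131.6 and 200.8 in the Arid2-labelled libraries and at 27.7 or below in the other 6.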

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

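Genes of developing T cells, which were too sparse across libraries to be tested or did not pass, were abundant in Arid2-labelled replicate 1. There Rag1 stood at 502.0 CPM, Rag2 at 26.8 CPM, Dntt, the terminal transferase of lymphocytes, at 153 CPM, Themis at 73.2 CPM and Ptcra, the pre-T-cell receptor alpha gene, at 1.80 CPM. They drew attention because each stands far above wild type, where the highest of these 5 genes reached 0.0569 CPM. In Smarcb1-labelled replicate 2 the same genes stood at 52.6, 3.55, 28.0, 10.2 and 0.136 CPM. The T-cell genes Cd4 and Cd8a stood at 161 and 212 CPM in the first of these libraries and at 31.1 and 44.9 CPM in the second.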

How the results depend on the processing

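Tests chosen after the result was seen are the GC-trend removal, the parathyroid covariate, both together, the omission of both thymus-marked libraries and the thinning. No paired analysis was possible because the labels give the groups no shared replicate numbers.

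The number of called genes, 95, 1349 and 2779 for Arid2-labelled against wild type, Smarcb1-labelled against wild type and Smarcb1-labelled against Arid2-labelled, changed as follows. At an adjusted p under 0.01 it was 8, 192 and 324, with the DESeq2 Wald test 904, 2784 and 4339, and with only the 6 libraries compared 201, 486 and 1348. With a fold of at least 2 it was 77, 491 and 1027. GC-trend removal gave 230, 418 and 1075, the parathyroid covariate 79, 197 and 145, both 156, 91 and 80, and omission of the thymus-marked libraries 56, 2166 and 3760; the covariate leaves fewer degrees of freedom (5) and the omission fewer libraries, and otherwise the cause was not tested. GC-trend removal moved the lower share of the first comparison from 57.9% to 69.6%, and it was 44.4%, 40% and 42.9% without Arid2-labelled replicates 1, 2 and 3. In the third, 57.3% were lower, against 47.97% with upper-quartile scaling, 47.7% with library totals and 75.3% at an adjusted p under 0.01; in the second, 72.7% became 91.7% at that threshold and 58.4% without Smarcb1-labelled replicate 2 (70.8% of the 1349 genes with the smallest p). Leaving out each library gave 5 to 167, 344 to 2538 and 395 to 4411. The other scalings, filters, voom, robust spread and thinning stayed within 1.5 times the main counts.

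The log2 fold change of Arid2 ranged from -0.03 to 0.28 and of Smarcb1 from -0.45 to -0.29 when 1 library was left out, with no call, and Arid2 was -0.0703 without the thymus-marked libraries; the DESeq2 Wald test called Smarcb1 (-0.38). The called lists, 9, 1 and 4, became 0, 0 and 0 with camera and an estimated correlation (2, 0 and 0 at an unadjusted p under 0.05) and 1, 0 and 1 with fry, the cartilage list both times. Leaving out each library gave 6 to 13, 0 to 4 and 3 to 7: for the second comparison 2 without Arid2-labelled replicate 3, 4 and 3 without Smarcb1-labelled replicates 1 and 2, and 2, 4 and 0 without wild-type replicates 1, 2 and 3, and for the third 7 without Smarcb1-labelled replicate 2. Without the thymus-marked libraries 3 were called in the second comparison. The shared count of 28 was 1 at an adjusted p under 0.01, 214 with DESeq2, 13 without the thymus-marked libraries and 1 to 37 without 1 library. The correlation of 0.345 was 0.0966 without the thymus-marked libraries and 0.127 to 0.590 without 1 library.

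Among named genes 3 changed sign where a value was called; uncalled ones, Arid2 among them, changed sign too. Krt4 in Smarcb1-labelled against wild type (0.37) had -4.59 without Smarcb1-labelled replicate 2, against at most 0.944 without any other library, and -4.62 without both thymus-marked libraries. Phlda3 and Cox4i1, lower in the third comparison, had 0.20 and 0.0700 with both added corrections. The cause was not tested. Depth limits genes such as Acan, with 2 wild-type counts and an interval of 5.55 to 173, while thinning left 91, 1314 and 2617 calls.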

Other observations

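The surfactant protein genes Sftpd and Sftpa1, singled out after their values were seen, were higher than in wild type in both labelled groups. Sftpd had a log2 fold change of 6.63 (adjusted p = 0.00834) in the Arid2-labelled and 3.32 (adjusted p = 0.0218) in the Smarcb1-labelled libraries, and Sftpa1 had 5.76 (adjusted p = 0.0132) and 3.79 (adjusted p = 0.0139), by edgeR. Sftpd stood at 2.76, 10.4 and 5.19 CPM in the Arid2-labelled libraries and at 0.0910 CPM or less in wild type. Sftpb stood at 6.13, 20.4 and 14.04 CPM in the Arid2-labelled, 1.22, 2.31 and 1.57 CPM in the Smarcb1-labelled and 1.64, 0.285 and 0.237 CPM in the wild-type libraries. Sftpc, the surfactant gene specific to the lung alveolus, stood between 0.229 and 1.30 CPM in all 9 libraries. Foxj1, a factor of ciliated cells, was low but highest in the Arid2-labelled libraries. It stood there at 0.991, 1.02 and 0.835 CPM, against 0.254, 0.588 and 0.298 CPM in the Smarcb1-labelled and 0.728, 0.711 and 0.119 CPM in the wild-type libraries. Other genes of the shared 28 were Dio3, the deiodinase that inactivates thyroid hormone, lower in both (-2.70 and -1.58), and Scarf2, lower in both (-1.16 and -2.01). Dio3 and Scarf2 lie outside the naming rule and were also singled out after their values were seen.

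Ucp1, the uncoupling protein of brown fat, stood at 691 CPM in wild-type replicate 3 and 494 CPM in Arid2-labelled replicate 3, against 27.4 to 299 CPM in the other 7. Calca, the calcitonin gene of thyroid C cells, ranged from 1348 to 4749 CPM. All 8 C-cell genes had negative fold changes in Arid2-labelled against wild type (median -0.35), with 0 calls by edgeR in either way of adjusting, 0 at an unadjusted p under 0.05, 0 by DESeq2 and no camera call (adjusted p = 0.205).

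Tests chosen after the result was seen are the GC and sex tests of the mostly lower calls, every test over a fixed number of genes, the GC test of the lower genes, and the parathyroid test of the higher genes; the fold change trend over GC content had been seen before every GC test. Calls in the Smarcb1-labelled libraries against wild type were mostly lower, 72.7% of 1349. The share was 79.4% of 418 calls with the GC trend removed, 85.3% of 197 with the parathyroid covariate, 84.6% of 344 without Smarcb1-labelled replicate 3, the only library with Xist and without Y-linked counts, 73.7% of 1314 after thinning to equal depth, and 58.4% of 2538 without Smarcb1-labelled replicate 2. Since such a share can move with the number of genes called, it was also taken over the 1349 genes with the smallest p in each fit: 68.7% with the GC trend removed, 70.4% with the covariate, 73.5% without Smarcb1-labelled replicate 3, 73.0% after thinning and 70.8% without Smarcb1-labelled replicate 2. Each is over the bound of 66%, but leaving out wild-type replicate 2 alone gave 67.7%, so these shares vary with single libraries. With the GC trend removed (418 calls) or the covariate (197 calls) most of the 1349 genes were not called. The same holds without Smarcb1-labelled replicate 3 (344 calls). The shares of 68.7%, 70.4% and 73.5% therefore do not decide those explanations. Thinning keeps each gene's expected share of the counts, so the folds were bound to stay close. The share after thinning does not decide about unequal read numbers. Lower genes were 84.6% of the 344 calls made without Smarcb1-labelled replicate 3, so the imbalance of those calls did not need that library. GC trend and covariate removed together gave 65.6%, just under the bound, so their joint part stays open. RNA quality and dissection were not tested, and the genotype may contribute, as a hypothesis from the same data.

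The single genes behind that imbalance rest on weaker ground. With the GC trend removed, 17.9% of the 368 higher genes (66) stayed called, under the bound of 25% set for this explanation before the result was seen; a stricter rule that also asked for a median fold no more than 0.5 times its size, tried after the result and dropped, would have left it open. Of the 981 lower genes 28.6% (281) stayed called, between that bound and the 50% that would have argued against it. The median fold of the higher genes went from 0.84 to 0.62, with a median SE of 0.19 before and 0.18 after. That of the lower genes went from -0.83 to -0.47, with 0.16 and 0.14. The folds thus shrank and the SE did not rise, but with fewer calls the adjustment also becomes stricter. Which of these ended the calls was not tested. A GC bias may account for part of the higher and of the lower calls. A GC trend simulated on unchanged genes called 0 genes without its removal, at the strength simulated. Of the higher genes 27.7% (102 of 368) lay lowest in the wild-type and the Arid2-labelled library without parathyroid markers, against 12.0% of all genes, between the 20% and 50% bounds, so parathyroid RNA cannot be told apart from the genotype label for them: Pth is at 5892 CPM or more only in the Smarcb1-labelled libraries. With the parathyroid covariate 25 of the higher and 167 of the lower genes stayed called. The median folds over all 368 and 981 genes, 0.79 and -0.79, were close to those before. The median SE rose from 0.187 to 0.219 and from 0.164 to 0.193. The covariate was higher in all 3 Smarcb1-labelled libraries (2.28 to 2.97) than in any other library (at most 1.83). It therefore overlaps with the label, and these losses decide neither for nor against parathyroid RNA as the source.

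The cell-cycle list was higher in the Arid2-labelled libraries, with a median of 1.33. Without Arid2-labelled replicate 1, the library rich in thymocyte genes, the median was 0.93 and the list stayed called, which argues against thymus cells as the whole cause though it leaves room for a part. Thinning to equal depth gave 1.29. Since thinning keeps each gene's expected share of the counts, the median was bound to stay close, and this value does not decide about library size. Cells dividing in the tissue of this genotype label may be a candidate source, a hypothesis that estimated correlation (adjusted p = 0.805) leaves open.

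Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. The real split called 95, 1349 and 2779 genes in the 3 comparisons, 1 of 10 splits each time, against at most 1, 2 and 1 in the others. For gene lists the real splits called 9, 1 and 4, and other splits up to 18, 19 and 14; 7, 10 and 10 of the 10 splits called as many. Splits that call as many lists as the real one or more could come from a structure of the samples other than genotype or from correlation between genes. Neither was tested on the splits. In the real comparisons camera with an estimated correlation called no list.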
